A study of Mus musculus with 26 samples.

How the data were processed

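H3K4me3 was profiled by ChIP-seq in Ebf1-null progenitors and in Early-B cells made from them, with 2 immunoprecipitated and 2 input DNA samples per group in the labels. Each group had 1 peak list, and its group was read from the list's name, which matches the titles of that group's samples. Per the submitters' processing notes, Bowtie 1.1.2, MACS 1.4.3 and the builds mm10 and GRCh38 are named, with no role given for each. The deposited columns are those that a later version of MACS writes for broad peaks, so which version made the lists is unsure. Whether replicates were pooled before calling, how the input was used and which settings applied are not given in the sources used here. The samples of microRNA sequencing and Ago2 immunoprecipitation were not used here.

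Each list gives a peak's chromosome, start, end and length, followed by values of the authors' peak caller. The pileup is a signal of read coverage as deposited by the authors. The fold enrichment is the authors' ratio of signal to a background. Whether these values and the p of a wide peak are averages over the peak or belong to its summit is not given in the sources used here. A further pair of deposited columns was read as −log10 p and −log10 q, from their values and order, since their names are damaged in the file headers. No q exceeds its p on this scale in either list. All these values are the authors' own and describe, rank or filter peaks within their list, and they do not measure change between lists. The lists are permissive: the lowest −log10 p is 1.01 in both, and 33.2% of Early-B and 33.4% of progenitor peaks have q above 0.05. No read counts or depths were used here, so no interval for counting error of reads could be given. Peaks fell on 20 chromosomes, with none on Y, and no peaks overlapped within a list.

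Coordinates are those of the files, counted from 1. They were joined to a gene table of GRCm38.p6, the assembly of mm10. As a check of the build, 83.2% of Early-B peaks and 83.9% of progenitor peaks with a −log10 p of at least 50 came within 1 kb of a protein-coding gene's end, against 18.2% and 17.6% after a shift of 100 kb. The table gives a start and an end per gene but no strand, start site or exon. The planned window of 1 kb around each transcription start site was therefore replaced by 1 kb around both ends of the gene's span, which also takes in peaks at the 3′ end and misses start sites inside the span. Location in exons and introns, the EBF1 motif test and random lists matched on GC content need sequence or exons and were not run.

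Peaks were compared with bedtools 2.31.1, a peak being shared when it overlapped at least 1 bp of a peak in the other list. All else was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Each of 21887 protein-coding genes was placed in both lists, Early-B only, progenitor only or neither. A microRNA was placed by peaks within 10 kb of its precursor. Of 397 entries in 16 gene lists, 395 were matched by symbol or synonym. For each list, the number of members in a class was set beside 10000 random lists of the same size drawn from genes with a peak in at least 1 list. These percentiles describe this pair of lists and are no test between conditions, since genes are not replicates. There were 30 such counts over the 15 protein-coding lists, with no correction across them. A second stromal list and a list of neural and endodermal regulators, 40 genes each, were added after the first stromal count was seen and before their own counts were. For both stromal lists, random lists were also drawn with each gene replaced by 1 of the 200 genes nearest in −log10 p.

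The gene lists, the alternatives and the genes to name were fixed before the data were examined, except where stated. The plan assumed a p on a log scale multiplied by 10, and its threshold was applied to the −log10 p as the same p. Named in the text were Ebf1, Pax5, Cd79a, Cd79b, Igll1, Vpreb1, Gata3, Tcf7 and Bcl11b whatever their result. Some genes that these rules name are counted in their lists and are not reported here by name. Added were up to 4 members per list and class, the 10 leading genes of each private class, the nearest genes of the 5 widest peaks per list, and up to 6 microRNAs per class, each by −log10 p. Other genes were named after their values were seen: further private members of the B lineage list, examples of genes in both lists or in neither, and the strongest private peaks.

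The steps were tested on simulated peak lists placed at 6000 isolated protein-coding genes. All 6000 genes were put in the class they were made with, all 15 planted Early-B-only genes of a list were found, no random list of 10000 reached that count, and 4 overlap rules gave the overlaps built in. The simulated peaks were centred inside the window of a gene end, so this checks the code only. Peak edges that miss a window, windows shared by neighbouring genes and the choice of gene end were not simulated.

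Alternatives covered the peak threshold (−log10 p of at least 10, fold of at least 10, FDR of at most 1%), equal list lengths, a strict threshold on the present side only, the overlap rule, gene windows of 500 bp and 2.5 kb, and microRNA windows of 2 and 20 kb. A count was called unchanged when within 1.5 times its main value, and a share when inside its exact 95% binomial interval.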

Results

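The series followed mouse progenitors that lack Ebf1, the transcription factor needed for B cell specification, and cells driven from them toward the B or the T lineage. Early-B cells were made by putting EBF1 back as a fusion switched on by 4-hydroxytamoxifen, with 2 days of culture on OP9 cells, a mouse stromal line, and cytokines. Early-T cells spent 5 days on OP9 cells that display the Notch ligand DL1. The labels list 26 samples, 2 per group and assay, covering microRNA sequencing, Ago2 immunoprecipitation of RNA, and chromatin immunoprecipitation of H3K4me3 with input DNA. H3K4me3 is a histone mark found at the start sites of active and poised genes. Analysed here was 1 H3K4me3 peak list from Early-B cells and 1 from Ebf1-null progenitors. The microRNA, Ago2 and Early-T samples were not analysed here. With 1 list per group there was no replicate check, and no difference below could be set against a spread between replicates. The lists hold no read counts, so the depth behind each peak is unknown.

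Ebf1 itself carried a broad H3K4me3 peak in both lists. On chromosome 11 (mm10) the Early-B peak ran from 44615552 to 44625444 with a −log10 p of 193, and the progenitor peak from 44616197 to 44626156 with a −log10 p of 221. Both lie across the lower-coordinate end of the gene, which spans 44618100 to 45008096. The Early-B list held 12 peaks in the gene and the 5 kb around it and the progenitor list 4. The Early-B peaks there that met no progenitor peak had −log10 p values of 9.45 or less. The position of the null allele's change is not given in the sources used here, so a peak at this end does not check the genotype. At Esr1, the estrogen receptor gene, the Early-B list held 9 peaks and the progenitor list 10. The strongest of them lay at the gene's lower-coordinate end in both lists, with a −log10 p of 69.8 in Early-B and 42.8 in progenitors.

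**Figure D1:**
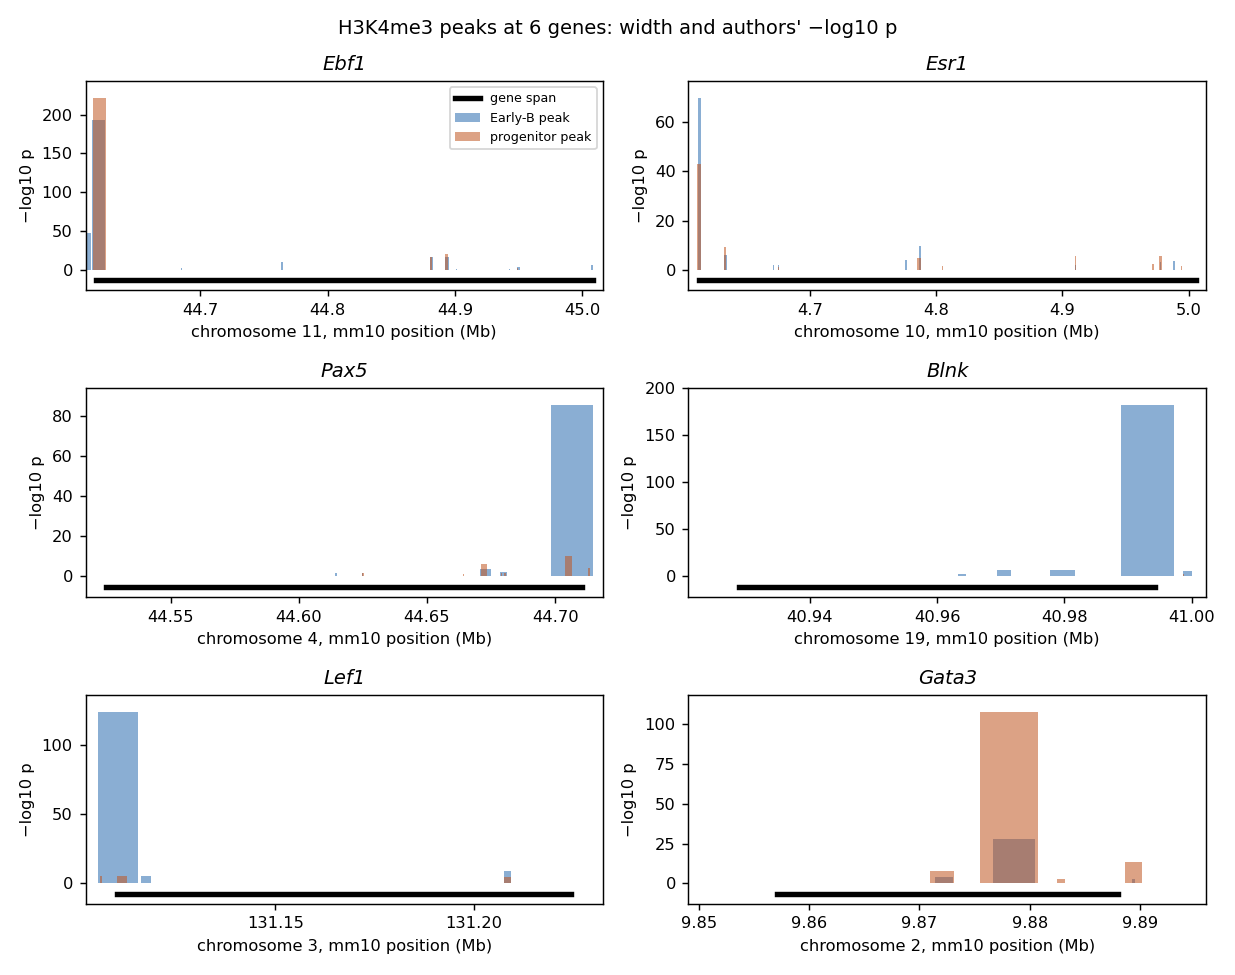
H3K4me3 peaks at Ebf1, Esr1, Pax5, Blnk, Lef1 and Gata3. Each bar spans a peak on the horizontal axis (mm10 position, Mb) and its height is the authors' −log10 p in that list (Early-B blue, progenitor orange, overlap darker), with the gene's span as a black line. Blnk has an Early-B peak of −log10 p 182 at its end and no progenitor peak within the gene, while at Ebf1 both lists have a strong peak.

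Over the whole genome, peaks were compared between Early-B cells and progenitors, which differ in EBF1 and may also differ in culture. The Early-B list held 48054 peaks covering 83.3 Mb and the progenitor list 31414 peaks covering 56.0 Mb. Median peak width was 1164 bp and 1231 bp. By an overlap of at least 1 bp, 23839 Early-B peaks (49.6%) met a progenitor peak, and 24265 progenitor peaks (77.2%) met an Early-B peak. The 24215 Early-B-only peaks had a median fold enrichment of 2.06 against 5.40 for the shared Early-B peaks, and the 7149 progenitor-only peaks had 1.79 against 4.84. The authors' q was above 0.05 for 51.1% of Early-B-only and 78.2% of progenitor-only peaks. Few strong peaks were private to a list: 173 Early-B-only peaks and 1 progenitor-only peak reached a −log10 p of 50. Which list was longer depended on the threshold. At a −log10 p of at least 50 the Early-B list held 9164 peaks and the progenitor list 9926, and at 100 they held 6489 and 8245.

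**Figure D2:**
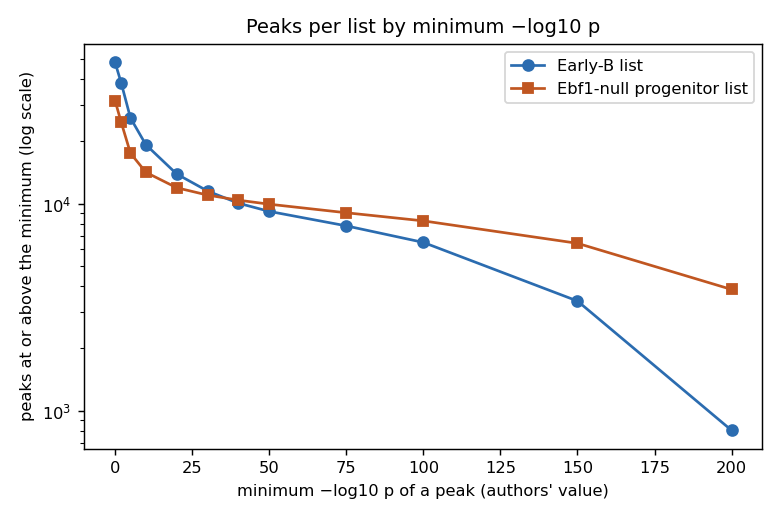
Number of peaks (vertical axis, log scale) whose authors' −log10 p reaches the minimum on the horizontal axis, for the Early-B list (circles) and the progenitor list (squares). The Early-B list is longer at low minimums, 48054 against 31414 peaks, and shorter from a minimum of 40 on, 10036 against 10381.

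The strongest private peaks lay at named genes. Blnk, which encodes an adaptor of B cell receptor signalling, led the Early-B-only peaks with a peak on chromosome 19 from 40988950 to 40997170 and a −log10 p of 182. It was followed by peaks within the centrosomal gene Cntln (127), at the shared end of Cnpy4 and Mblac1 (122), at Enpep (118), and at Eng, the endothelial co-receptor endoglin (113). Cnpy4, Enpep and Eng each also had another peak at a gene end in the progenitor list, with −log10 p values of 246, 5.01 and 2.48. The progenitor-only peaks were led by Cited4, a transcriptional co-regulator (chromosome 4, 120666402 to 120668340, −log10 p 52.2), Ajap1 (37.0), Glp1r (33.6), Egfem1 (31.8) and Bik, a pro-apoptotic BCL2 family member (30.8). Glp1r also had another Early-B peak at a gene end (4.13). These 10 peaks were chosen after their values were seen.

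Shared peaks lay at the ends of protein-coding genes far more often than private ones. Of shared peaks, 44.1% in the Early-B list and 43.1% in the progenitor list came within 1 kb of a gene end, against 5.99% of Early-B-only and 9.72% of progenitor-only peaks. Early-B-only peaks lay mostly outside protein-coding genes (59.2%), while progenitor-only peaks lay mostly inside them (54.2%). Shared peaks were also wider than private ones, with medians of 2122 and 731 bp in the Early-B list and 1664 and 589 bp in the progenitor list. A wider peak meets a gene-end window and a peak of the other list more readily, and width was not held equal here.

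Of 21887 protein-coding genes, 11710 (53.5%) had a peak within 1 kb of a gene end in both lists, 1259 in Early-B only, 512 in progenitors only and 8406 in neither. The gene table gives no strand, so either end of a gene was taken. Of the Early-B-only genes, 166 had a peak that overlapped a progenitor peak reaching less far, as did 56 of the progenitor-only genes in reverse. That effect dominates the genes with the highest −log10 p. Of the 10 leading Early-B-only genes, among them Efcab12, Blnk, Rad21, Ddx56, Slc4a9, Lmbrd1, Stambpl1, Bpifc and Trim66, 9 had a peak overlapping a progenitor peak, the exception being Blnk. All 10 leading progenitor-only genes (Zdhhc7, D130037M23Rik, Smim40, Morn1, Igflr1, Pde6b, Masp2, Pnpla3, Trim11 and Ppm1h) had a peak overlapping an Early-B peak. The class of a gene with such a peak rests on a peak edge. Genes such as Dnmt1, Dnmt3a and Ywhaz, whose only strong peaks lie further inside the annotated span, count as neither. A fold of at least 10 was passed unequally by the lists, in a tally made after seeing the data. Of the 11710 genes in both lists, 9523 had a progenitor end peak at that fold and 8663 an Early-B one, as did 15 and 12 of the 15 housekeeping genes. Class counts at that threshold carry this limit.

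B-lineage genes were the lymphoid list with the most Early-B-only members. Of 35 with a peak, 11 were Early-B only, 24 were in both lists and none was progenitor only. Among the 11 were Cplx2 (−log10 p 100.2), Pax5, the factor that commits cells to the B lineage (85.6), the B cell lectin Cd22 (82.3), the surrogate light chain gene Igll1 (72.9), the co-activator Pou2af1 (69.2), Bst1 (49.0), Dntt (40.8), Vpreb2 (17.0), Ikzf3 (11.3) and Ms4a1 (1.83). Random lists of 35 genes with a peak held 3.25 Early-B-only genes on average, and 5 of 10000 held 11 or more. This count rests partly on where peaks end. At 4 of the genes, Pax5, Igll1 and Dntt among them, the Early-B peak overlapped progenitor peaks that lay outside the window. With a 2.5 kb window 6 genes were Early-B only, a count that 1619 of 10000 random lists reached, and with a peak anywhere in the gene, an alternative chosen after seeing the data, 7 were, reached by 1038. With a 500 bp window 12 were Early-B only, reached by 2, and at equal list lengths 10 were, also reached by 2.

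Of the 24 B-lineage genes in both lists, 17 had the wider peak in Early-B, while at Ebf1, Rag1, Rag2, Bach2, Ikzf1, Sox4 and Myb the progenitor peak was wider. The wider peak was also the Early-B one at 14 of 15 housekeeping genes and 15 of 17 genes of IL-7 and FLT3 signalling, and over all one-to-one shared peaks in 62.9%. Other lists went the other way, with the wider peak in Early-B at 3 of 15 stem genes and 1 of 10 NK genes. The Early-B peak at Pax5 covered 16264 bp on chromosome 4, from 44698526 to 44714789, and the progenitor list had a 2754-bp peak (−log10 p 10.0) and a 914-bp peak (3.99) inside that stretch. Igll1 and Vpreb1, the surrogate light chain pair, shared an 18321-bp Early-B peak on chromosome 16 that also reached Top3b. Vpreb1 counted as both because of a 2891-bp progenitor peak (179) that also reached Top3b, so which gene it belongs to is open. Cd79a and Cd79b, the signalling chains of the B cell receptor, had a peak in both lists. At Cd79a the Early-B peak, from 24895463 to 24907800 on chromosome 7, covered the whole gene and reached Arhgef1. The progenitor peak ran from 24901798 to 24908386, also reached Arhgef1, and met only the end of Cd79a at 24901858. Which gene that progenitor peak belongs to is open. At Cd79b the peak covered 12576 bp in Early-B (−log10 p 39.7) and 1266 bp in progenitors (4.24). At Lef1 it covered 9877 bp (124) and 2431 bp (5.57).

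Among 18 genes of B cell receptor signalling, 17 had a peak in both lists and Blnk alone was Early-B only. Random lists held 1 or more Early-B-only genes in 8276 of 10000 draws.

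T-lineage and Notch genes were mostly in both lists, with few private members at the deposited threshold. Of 26 with a peak, 22 were in both lists, Cd5 (12.5) and Cd8b1 (3.99) were Early-B only, and 2 were progenitor only, Gata3 (13.4) among them. Random lists reached 2 Early-B-only genes in 7061 of 10000 draws and 2 progenitor-only genes in 2569. These counts depended on the threshold: with a −log10 p of at least 10 in both lists 5 were Early-B only (112 of 10000 random lists) and 5 progenitor only (105). Progenitor-only genes numbered 4 at a fold of at least 10 (38), 4 at an FDR of at most 1% (194) and 5 at equal list lengths (254), and none with a 500 bp window or a peak anywhere in the gene. Gata3, a factor of early T cell development, had its strongest peak inside the gene in both lists, with a −log10 p of 108 in progenitors and 27.8 in Early-B, so its class rests on the smaller peak at its end. A 348-bp Early-B peak (2.91) overlapped that end peak and lay just outside the window. Tcf7, another early T cell factor, had an end peak in both lists, 4593 bp wide in progenitors (21.6) and 1706 bp in Early-B (4.49). Bcl11b, needed for T cell commitment, had no peak in either.

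At the deposited threshold, stem and multipotent progenitor genes went the other way from B-lineage genes. Of 19 with a peak, 15 were in both lists and 4 were progenitor only: Gata2 (−log10 p 8.41), Lmo2 (5.44), Hlf (5.36) and Erg (2.59). None was Early-B only. Random lists reached 4 progenitor-only genes in 56 of 10000 draws. Lmo2 also had a strong peak inside the gene in both lists, and Erg (27.5) and Gata2 (4.83) had an Early-B peak inside the gene. With a −log10 p of at least 10 in both lists 1 stem gene was progenitor only (5486 of 10000 random lists) and 1 Early-B only (5612). All 4 end peaks had a −log10 p below 10, so none counted when at least 10 was asked of the progenitor peak, and with a peak anywhere in the gene 1 gene was progenitor only. With a fold of at least 10 asked in both lists 8 genes were progenitor only (0 of 10000 random lists). That setting put 1117 genes of all kinds in the progenitor-only class, 3 housekeeping genes among them (2322), against 512 at the deposited threshold.

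Myeloid, erythroid and NK genes gave few private members at the deposited threshold. Of 15 myeloid genes with a peak, Mpo (7.23) and Itgam (4.73) were progenitor only. Of 11 erythroid and megakaryocyte genes, the globin genes Hbb-bt (7.29) and Hbb-bs (3.73) were progenitor only and Pf4 (5.59) Early-B only. Of 12 NK and innate lymphoid genes, Klrk1 (4.32) was Early-B only and Klrd1 (1.87) progenitor only. The Early-B peak at Klrk1 overlapped a progenitor peak. The end peak of Klrd1 had q above 0.05, and inside that gene the Early-B list had the stronger peak (27.7, against 11.8 in progenitors). Random lists reached the progenitor-only counts of the myeloid, erythroid and NK lists in 1076, 584 and 3717 of 10000 draws. With a fold of at least 10 in both lists 7 myeloid genes were progenitor only (0 of 10000 random lists), where 3 housekeeping genes were too (2322), and with a −log10 p of at least 10 none was. NK progenitor-only genes numbered 3 with a −log10 p of at least 10 (70), a fold of at least 10 (51), an FDR of at most 1% (81) and equal list lengths (380), and 0 when the Early-B list kept its deposited threshold against a progenitor −log10 p of at least 10.

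Stromal and mesenchymal genes held the highest share of Early-B-only members of the 15 protein-coding lists. Of 18 with a peak, 11 (61.1%, exact binomial 95% interval 35.7 to 82.7%) were Early-B only, 7 were in both and none was progenitor only. The 4 with the highest −log10 p were Sparc (35.0), Postn (12.4), Pparg (8.72) and Lox (7.41), and 9 of the 11 lay below 10. None of 10000 random lists reached 11, against a mean of 1.67. Per the labels the Early-B cells were grown on OP9 stromal cells, and the progenitors' culture is not stated there. When an Early-B −log10 p of at least 10 was asked for, Sparc and Postn were left, a count that 298 of 10000 random lists reached. Both peaks lay at the lower-coordinate end of their gene. Without strand, whether that end holds the start site or is the 3′ end is unknown here. With at least 10 asked in both lists 3 were Early-B only (50 of 10000) and 3 progenitor only (30). At equal list lengths 10 were Early-B only, reached by 0 of 10000. With a fold of at least 10 in both lists none was Early-B only, a setting that left 312 such genes of all kinds against 1259. That setting cannot speak to the excess, because no stromal end peak passed it in either list. The fold at Sparc was 6.98.

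MHC class II genes had 2 Early-B-only members of 8, H2-Aa (18.1) and H2-DMb1, as many as in 1673 of 10000 random lists. With a −log10 p of at least 10 in both lists 3 were, reached by 62, and with a fold of at least 10 none was. All genes with a peak were in both lists for IL-7 and FLT3 signalling (17 genes), TGF-beta and SMAD signalling (15), chromatin regulators (18) and housekeeping genes (15). The microRNA machinery had 17 genes in both, Drosha, Dicer1 and Ago2 among them, and 1 progenitor-only gene, Lin28b (5.71). Lin28b also had a stronger Early-B peak inside the gene (10.8), so its class rests on the end window. Of 18 control genes of other tissues, 15 had no peak at a gene end in either list, 2 were in both and Nphs1 (1.58) was Early-B only. With a peak anywhere in the gene 4 were Early-B only, Ttn, Myh6, Myh7 and Tnnt2 (43 of 10000 random lists), and 2 were progenitor only at an FDR of at most 1% (22) and at equal list lengths (50), so these controls were not free of private peaks.

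**Figure D3:**
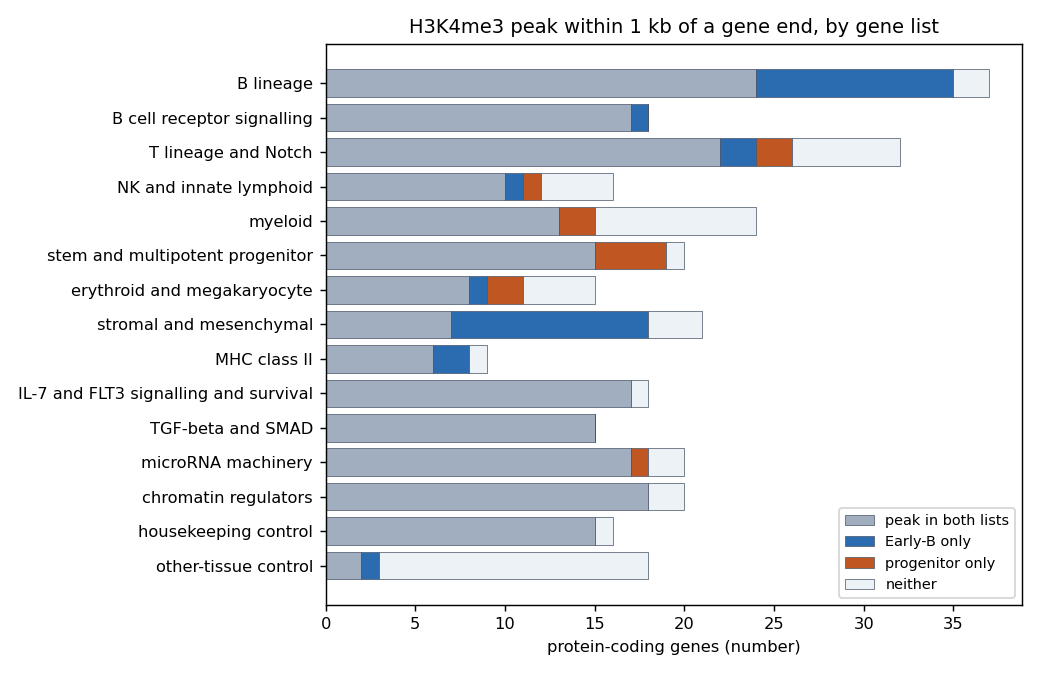
Number of protein-coding genes (horizontal axis) of each fixed list by H3K4me3 class, a peak within 1 kb of a gene end in both lists (grey), Early-B only (blue), progenitor only (orange) or neither (pale). The B lineage and stromal lists each hold 11 Early-B-only genes, and the stem list holds 4 progenitor-only genes.

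MicroRNA genes were examined because the series concerns microRNAs in lineage choice. Of 1228 annotated precursors, 670 had a peak within 10 kb, 522 of them in both lists, 108 in Early-B only and 40 in progenitors only. Of the 72 lymphoid microRNAs with a peak, 54 were in both, among them Mir17, Mir142, Mir150, Mir155 and Mir223. Early-B only were 11, led by Mir100 (−log10 p 21.1), Mir26a-1 (10.2), Mir148a (9.45), Mir342 (5.04), Mir125b-1 (4.90) and Mir125b-2 (3.46). Progenitor only were 7: Mir29a and Mir29b-1, which share a peak (5.72), Mir744 (2.70), Mir221 and Mir222, which share another (2.28), Mir26a-2 (2.26) and Mir28a (1.20). Random lists of microRNAs reached these counts in 6344 and 1215 of 10000 draws, so neither stood apart. Clustered microRNAs share peaks and are not independent, and a peak within 10 kb can belong to a neighbouring gene.

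The antigen receptor loci differed most at Igk, the kappa light chain locus. Over its 3171 kb on chromosome 6 the Early-B list held 119 peaks, of which 116 met no progenitor peak and 21 had a −log10 p of at least 10. The progenitor list held 7 peaks there, 1 of them with a −log10 p of at least 10 (64.5), against a highest value of 34.2 in the Early-B list. Igh, the heavy chain locus, held 121 Early-B and 82 progenitor peaks, and the T cell receptor alpha and delta locus 83 and 65. With a −log10 p of at least 10 the order turned, to 9 and 10 peaks at Igh and 21 and 31 at the alpha and delta locus. Tcrb held 15 and 13 peaks, Tcrg 15 and 14, and Igl 5 and 1. The Early-B list was longer throughout the genome, and these counts are not scaled for that.

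The widest peaks of each list were described by their nearest genes. Ends of Hoxa3, Hoxa7, Hoxa9 and Hoxa10, homeobox genes, lay at the widest Early-B peak, 24716 bp on chromosome 6, and at a 26068-bp progenitor peak. The next Early-B peaks were a 21784-bp peak 48817 bp from Ppara, one over Hnrnpf and 4933440N22Rik (21680 bp), the one over Igll1 and Vpreb1, and one over the cell cycle inhibitor Cdkn1b (17649 bp). The widest progenitor peak, 87215 bp on chromosome 8 from 123537238 to 123624452, covered 48 annotated rRNA genes beside Gas8, and 12 Early-B peaks overlapped it, with a highest −log10 p of 5.38. It was followed by the Hoxa peak and by peaks over Rhof and Setd1b (20954 bp), Mn1 (20656 bp) and B3gnt2 (20298 bp).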

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

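Chosen after seeing the data were the thresholds for list length, a peak anywhere in the gene, peaks overlapping no peak of the other list, and genes with unshared windows. No paired analysis was possible because the lists carry no values per replicate, although the labels share replicate numbers; for the same reason no replicate was left out. Also not run were the 5′-end start sites, GC-matched random lists and both EBF1 motif alternatives, which need strand or sequence. Stricter thresholds left 19227 Early-B and 14148 progenitor peaks at −log10 p of at least 10 (difference 5079), and 29336 and 19331 at FDR of at most 1% (10005). The order turned at fold of at least 10, with 8338 and 9374 (-1036), and at −log10 p of at least 50, with 9164 and 9926 (-762); the cause was not tested. At fold of at least 10, 3 housekeeping genes became progenitor only and none Early-B only, and the progenitor-only counts there, 8 stem and 7 myeloid genes included, carry that limit. Among genes in both lists, that fold was passed in progenitors and in Early-B by 12 and 4 of 15 stem genes and by 9 and 2 of 13 myeloid genes. For 24 B-lineage genes it was 12 and 12. A gene-by-gene comparison of housekeeping fold between the lists, made after the housekeeping pattern was seen, is not reported because the authors' fold is used within a list only. Only the tally of genes that pass a fold of at least 10 within each list is given. Shared shares of Early-B and progenitor peaks were 63.7% and 87.1% at −log10 p of at least 10 in both lists, leaving 6984 and 1828 private peaks. They were 94.3% and 84.3% at fold of at least 10 (478 and 1471 private), 55.3% and 84.6% at FDR of at most 1% (13117 and 2972), and 63.8% and 65.7% at equal list lengths (11368 and 10790). With the strict threshold on the present side only they were 78.9% and 99.3% (4060 and 101). Overlap of at least 50% of both peaks gave 35.9% and 54.9%, with 14177 progenitor-only peaks, of the shorter peak 76.6% of progenitor peaks, and peaks within 1 kb 50.4% and 78.4%. Counting all sequences changed nothing, since the lists hold standard chromosomes only. Early-B-only genes numbered 672 at −log10 p of at least 10, 312 at fold of at least 10 and 383 with the one-sided threshold; progenitor-only genes 1117 at fold of at least 10, 837 at equal lengths and 84 one-sided. Unshared windows left 6316 genes in both, as fewer genes enter. B-lineage Early-B-only genes numbered 7 at fold of at least 10, reached by 0 of 10000 random lists, and 6 with 2.5 kb (1619). They numbered 7 with a peak anywhere in the gene (1038) and 7 without overlapping peaks (176). They numbered 16 at −log10 p of at least 10 in both lists (0) and 13 at FDR of at most 1% (0). At equal lengths they were 10 (2), with 500 bp 12 (2) and one-sided 10 (0). Their progenitor-only count of 0 became 1, 2, 1 and 1 at −log10 p of at least 10, fold of at least 10, FDR of at most 1% and equal lengths. Stem progenitor-only genes numbered 1 at −log10 p of at least 10, 8 at fold of at least 10, 0 one-sided and 1 anywhere in the gene, and 1 stem gene became Early-B only at −log10 p of at least 10. Stromal Early-B-only genes numbered 3 at −log10 p of at least 10, where 3 others were progenitor only, and 2 one-sided. They numbered 0 at fold of at least 10, which no stromal end peak passed in either list. At equal lengths they were 10 and at FDR of at most 1% 13, each reached by 0 of 10000 random lists. With 2.5 kb they were 9 and with 500 bp 13, also reached by 0. All microRNAs in Early-B only numbered 47, 14, 56 and 23 at −log10 p of at least 10, fold of at least 10, equal lengths and one-sided, and 48 within 2 kb; progenitor-only ones 25, 66, 66 and 2, and 26 at FDR of at most 1%. Lymphoid microRNAs in Early-B only numbered 2, 1, 6 and 2 at those first 4 settings, 6 at FDR of at most 1% and 6 within 2 kb; progenitor-only ones 0 at −log10 p of at least 10 and one-sided, 3 at FDR of at most 1%, 3 within 2 kb and 4 within 20 kb. For the other gene lists 151 of 216 counts stayed within 1.5 times and 65 moved further. Of 94 named genes and microRNAs 56 changed class at fold of at least 10, 36 at −log10 p of at least 10 and 34 one-sided, and of 76 genes 35 did with a peak anywhere in the gene; none turned from Early-B only to progenitor only or back. Depth is unknown, so how far it sets the number of weak peaks in a list was not tested.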

Other observations

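In the Hoxb and Hoxc clusters more homeobox genes had an end peak in the Early-B list than in the progenitor list. The counts were 6 and 1 at Hoxb and 5 and 2 at Hoxc. In the Hoxb cluster on chromosome 11, 5 of 10 genes were Early-B only (Hoxb13, Hoxb8, Hoxb7, Hoxb6 and Hoxb2) and none was progenitor only. Hoxb6 had a 4918-bp Early-B peak from 96291134 to 96296051 with a −log10 p of 97.2. That peak also met the edge of the 1 kb window of Hoxb7, which ends at 96290163, so the class of Hoxb7 rests on a window edge. In the Hoxc cluster Hoxc11, Hoxc10, Hoxc5 and Hoxc4 were Early-B only and Hoxc6 was progenitor only. In the Hoxd cluster Hoxd8 was progenitor only and no gene was Early-B only. In the Hoxa cluster 11 of 11 genes had an Early-B peak and 10 a progenitor peak. With a −log10 p of at least 10 it was 6 and 7 genes, and the highest value was 37.8 in Early-B and 144 in progenitors. These clusters were chosen after their values were seen, no random lists were drawn for them, and neighbouring genes can share a peak. On the X chromosome 62.4% of the 1667 Early-B peaks met no progenitor peak, against 50.4% over all chromosomes, while 18.3% of the 778 progenitor peaks there met no Early-B peak, against 22.8%.

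Regulators of neural and endodermal fates had few peaks, and these were often private. Of 40 genes 15 had a peak. Neurod1, Gata6, Dlx5 and Emx2 were Early-B only, a count reached by 434 of 10000 random lists. Neurog1, Neurog2, Nkx2-2, Foxa1 and Cdx2 were progenitor only, a count reached by 2 of 10000, but the progenitor peak overlapped no Early-B peak at only 2 of them. The list was added after the first stromal count was seen.

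Chosen after the result was seen were both tests for B-lineage genes, the stromal test matched on the Early-B −log10 p and both matched tests of the second stromal list. The stromal excess in Early-B only (11 of 18 genes) was set against chromatin of OP9 cells, the stroma of the Early-B culture, as a hypothesis: a further list of 40 stromal genes, sharing none with the first, had 22 Early-B-only genes of 35 with a peak (13 in both lists), reached by 0 of 10000 random lists, though 21 of the 22 peaks had a −log10 p under 10. A longer Early-B list that adds peaks at any gene of like peak strength is argued against as the whole cause, mainly by the second list. The matching was on −log10 p only, so a longer list that favours genes of this kind is not addressed. Of 10000 random lists matched on the higher −log10 p, 163 reached the first list's count and 12 the second's. Of those matched on the Early-B −log10 p, 143 and 2 did. The first list had the highest Early-B-only share of the protein-coding lists, so its matched counts carry that selection. The matched means of 6.20, 13.5, 6.12 and 12.5 show that genes of like peak strength give much of both counts. More weak peaks at genes without a strong mark in blood cells stay open: 26.7% (exact 95% interval 7.79 to 55.1%) of the neural and endodermal genes were Early-B only, which overlaps the stromal interval, and the class of Foxa1 was known when that test was written. Stromal chromatin may contribute to the Early-B list, but with a −log10 p of at least 10 in both lists 3 stromal genes were Early-B only and 3 progenitor only, Col1a1 was in both lists (−log10 p 8.66 in Early-B, 5.46 in progenitors), Dcn, Lum and Tagln in neither, and an effect of EBF1 on these genes was not tested and stays open.

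The B-lineage excess in Early-B only was set against a longer list of weak peaks and against peak edges. Weak Early-B peaks do not make up most of the count. When an Early-B −log10 p of at least 10 was asked for, 10 of the 11 genes stayed Early-B only, all but Ms4a1. No progenitor peak at all was allowed in the window, and 0 of 10000 random lists reached that count. Those random lists were not matched on peak strength and the test was chosen after the result was seen, so their figure only describes the count. Peak edges stay open, because 36.4% (4 of 11) of the genes had an Early-B peak that overlapped a progenitor peak. The pattern could thus combine peaks private to Early-B, as at Cd22, Pou2af1 and Cplx2, with Early-B peaks that reach past smaller progenitor ones, as at Pax5. A difference in EBF1 between the groups is the design's biological explanation and was not tested. It cannot be told apart here from the fusion, the 4-hydroxytamoxifen or the culture on OP9 cells with cytokines. The progenitors' culture is not stated in the labels.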
